A study of Homo sapiens with 6 samples.

How the data were processed

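The data were gene counts from 6 libraries of the cell line OCI-AML2, 3 treated with 100 nM MRT199665 and 3 with vehicle for 48 h. Groups and replicate numbers were taken from the labels. The labels give a Lexogen kit for 3′ messenger RNA sequencing and say that clones grown from single cells were cultured. They do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1 and DESeq2 were used with the hg19 build. Which annotation, strand setting and read filters were used is not given in the sources used here. The deposited table holds whole-number counts per gene that were not normalized, as tested on its values, under gene symbols without coordinates. No coordinates are given, since the reference used here, GENCODE release 29, is on a later build. That reference served only for gene types and GC content, and older symbols of list members were matched through a RefSeq table.

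Genes were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest with default settings, TMM scaling, group as the only term). The filter was filterByExpr with a minimum count of 10 and minimum total of 15, which left 13053 of 55765 genes. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The SE of a log2 fold change was its size divided by the square root of F. CPM values were computed on totals scaled by TMM. Fold changes are MRT199665 over vehicle, or vehicle over MRT199665 where a gene was lower. The libraries were checked only for 1 library deposited under more than 1 name. Chi-square per degree of freedom was 9.71 or more between libraries of a group, so none was treated as such a copy, which does not show that they came from separate cultures.

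A total of 39 gene lists were written from general knowledge before the data were examined, as were the main test, the naming rule and most alternatives. Each list with at least 3 tested genes was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with a correlation estimated per list, with fry and with cameraPR. List p-values were adjusted over the 39 lists. Members were also counted when adjusted over the list alone. Genes were named by a fixed rule. It took the 10 called genes with the greatest fold change in each direction that had non-overlapping groups, a symbol that was not a clone, LOC, LINC, MIR or open reading frame name and a mean of at least 5 CPM in the higher group. It also took the MEF2, MARK, SIK and class IIa deacetylase genes, up to 4 called members with the lowest p of each list described, or up to 2 where none was called, and the 5 called genes per direction with the lowest p and at least 100 CPM in both groups (4 lower genes met this).

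Alternatives were other scalings and low-count filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, a threshold of 1.5-fold, and leaving out each library in turn. Added after seeing the data were the newer quasi-dispersion of edgeR, removal of a GC trend (last 500 bases of transcripts, lowess span 0.3, available for 89.76% of tested genes) and leaving out both ends of the first principal component. On counts simulated for 13053 genes of this comparison, the test called 8.96% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 8 false calls among 113. In simulated data without change no gene and no list was called. Genes were simulated independently of each other, so this cannot show how often lists are called when genes vary together.

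Metallothionein, histone, class II, LILR and ribonuclease genes have close copies, and reads could be split between them in ways that the sources used here do not give. Reads of a gene and its antisense partner cannot be told apart without the strand setting. Depth ranged from 5871097 to 14308650 counts, so small changes of genes at few CPM were not detectable.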

Results

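Gene expression was measured in OCI-AML2, a human cell line established from acute myeloid leukaemia, after 48 h with 100 nM MRT199665 or with vehicle alone. MRT199665 is named in the labels as an inhibitor of the MARK kinases, which phosphorylate microtubule-associated proteins, and it is also known to inhibit the related SIK kinases. The libraries were made by sequencing from the 3′ ends of messenger RNAs, and each group held 3 libraries. The deposited table gave counts for 55765 genes, of which 28230 had a count in at least 1 library. Total counts were 11851457, 11994657 and 9517907 in vehicle replicates 1, 2 and 3, and 13446613, 5871097 and 14308650 in MRT199665 replicates 1, 2 and 3. A count of 3, taken as the limit that a count of 0 allows, corresponded to between 0.210 and 0.511 CPM (counts scaled to a common library size), and this limit covers counting error only. The series title places the experiment in a study of MEF2C phosphorylation and the response of leukaemia cells to chemotherapy. The comparison asked which transcripts differed between inhibitor and vehicle.

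The libraries differed among themselves as well as by treatment. The first principal component held 46.75% of the variance and did not separate the groups, with MRT199665 replicate 2 at 48.4 and vehicle replicate 2 at -36.8. The second component held 26.25% of the variance. It placed the vehicle libraries between 0.954 and 35.3 and the MRT199665 libraries between -26.4 and -5.94. The ribosomal protein gene RPL27A took the largest share of counts in each library, from 4.70% to 7.34%.

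**Figure D1:**
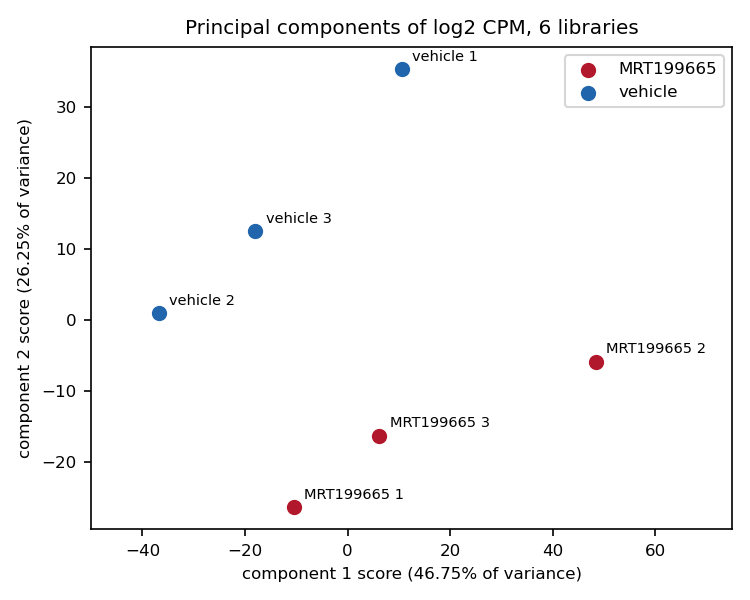
Scores of the 6 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, coloured by group. The second component separates the groups, with all vehicle libraries at 0.954 or above and all MRT199665 libraries at -5.94 or below, while the first spreads libraries within both groups.

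With MRT199665 the cells had more transcripts of monocyte and macrophage genes and of several major histocompatibility complex class II genes, and fewer of several metallothionein and stress response genes. CSF1R, the receptor for macrophage colony-stimulating factor, was 5.09-fold higher, at 41.1 ± 3.35 CPM against 8.08 ± 1.17 CPM with vehicle (SD, n = 3 per group). CD86, a co-stimulatory ligand of antigen-presenting cells, was 8.20-fold higher, at 14.9 ± 2.04 against 1.80 ± 0.445 CPM (SD, n = 3 per group). MT1G, a metal-binding metallothionein, was 12.5-fold lower, at 3.71 ± 1.40 against 44.0 ± 5.84 CPM (SD, n = 3 per group). ASNS, which synthesises asparagine, was 3.32-fold lower, at 80.2 ± 16.3 against 267 ± 20.6 CPM (SD, n = 3 per group). Of 13053 genes tested, 111 were higher and 52 lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and each of the 163 changed by at least 1.5-fold. All 163 had no overlap between the groups' libraries, as did 2895 of all tested genes (22.18%, against 10% by chance). Leaving out MRT199665 replicates 1, 2 and 3 in turn gave 57, 68 and 36 higher and 22, 31 and 20 lower genes, and leaving out vehicle replicates 1, 2 and 3 gave 78, 65 and 29 higher and 55, 29 and 20 lower. DESeq2 called 215 higher and 148 lower genes, and edgeR without a low-count filter called 373 and 271.

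**Figure D2:**
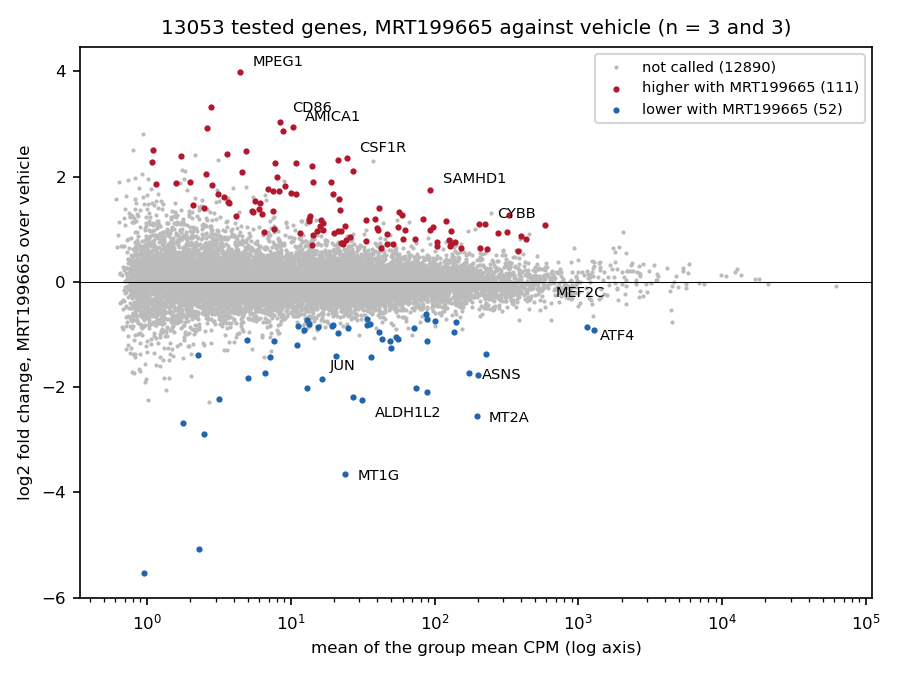
Log2 fold change (MRT199665 over vehicle, vertical) against mean CPM of the groups (horizontal, log axis) for the 13053 tested genes, with 1 point per gene. The 111 genes called higher and 52 called lower are coloured, and MEF2C lies near 0 at a log2 fold change of 0.04.

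Of the 10 higher genes with the greatest fold changes that met the naming rule, MPEG1, a perforin-like protein of macrophages, was 15.9-fold higher, with a log2 fold change of 3.99 ± 0.42 (SE). NTN1, a netrin guidance cue, was 9.99-fold higher, and AMICA1, a leukocyte adhesion molecule, 7.73-fold higher (log2 fold change 2.95 ± 0.18, SE, adjusted p = 0.000694). With vehicle, MPEG1 and NTN1 had means of 0.524 and 0.485 CPM, near the detection limit given above. Each had 17 counts over the vehicle libraries, so the size of these folds is uncertain. Over the alternatives their log2 fold changes lay between 3.46 and 4.40 for MPEG1 and between 2.90 and 3.94 for NTN1. LILRB2, an inhibitory leukocyte receptor, was 7.30-fold higher, followed by ADAM28 (5.60-fold), the cannabinoid receptor gene CNR2 (5.38-fold) and the uroplakin gene UPK3A (4.80-fold). CD86, CSF1R and the class II gene HLA-DRA were also among these 10 genes. Among abundant genes, at 100 CPM or more in both groups, those with the lowest p were CYBB, S100A4, FAM43A, TYROBP and KCNE1L. S100A4, a calcium-binding protein, was 2.12-fold higher, at 792 ± 14.3 against 374 ± 39.7 CPM (SD, n = 3 per group), and FAM43A and the potassium channel subunit gene KCNE1L were 1.91-fold and 1.84-fold higher. Without vehicle replicate 3 the calls of UPK3A (adjusted p = 0.0597), S100A4 (0.0597), FAM43A (0.0684), TYROBP (0.0971) and KCNE1L (0.109) ended. Without MRT199665 replicate 3 those of NTN1 (adjusted p = 0.0615), TYROBP (0.0643) and KCNE1L (0.0819) ended.

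The fixed list of monocyte and macrophage maturation genes was higher as a group (median log2 fold change 0.79, camera adjusted p = 1.14e-13). It was also called with an estimated correlation (adjusted p = 0.0409). The list held 38 genes, of which 28 were tested and 25 had a positive log2 fold change. Among those not tested, CD14 had means of 0.839 CPM with MRT199665 and 0.567 CPM with vehicle (unscaled totals). VCAN and FCN1 were lower still. Of the tested members, 7 rose at the threshold over all genes, and 18 rose when adjusted over the list alone. CYBB, the catalytic subunit of the phagocyte oxidase, was 2.14-fold higher at 305 ± 5.80 against 143 ± 8.39 CPM (SD, n = 3 per group). MS4A6A, a membrane protein of monocytes, was 2.42-fold higher, and TYROBP, a signalling adaptor of myeloid receptors, 1.94-fold higher. The primary granule list was higher by camera (3 of 14 members called, 9 adjusted over the list alone, adjusted p = 7.21e-05), but not with an estimated correlation (adjusted p = 0.220). Its called members were the ribonuclease genes RNASE3 (1.91-fold) and RNASE2 (1.57-fold), which share sequence, and CFD (2.13-fold), the complement factor D gene. RNASE2 lost its call without each of the 6 libraries (highest adjusted p = 0.263, without vehicle replicate 3). RNASE3 lost it without MRT199665 replicate 2 or 3 or any vehicle library (highest 0.157, without MRT199665 replicate 3), and CFD without MRT199665 replicate 3 or any vehicle library (highest 0.202, without vehicle replicate 3). TRAC, the T cell receptor alpha constant gene, also rose 2.09-fold (adjusted p = 0.0167), and was not called without MRT199665 replicate 1 (0.0674) or 3 (0.118) or vehicle replicate 3 (0.105). The list of T and NK cell markers, with 3 of 18 genes tested, was not called (adjusted p = 0.153).

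Antigen presentation genes were higher as a list (camera adjusted p = 0.000525), with 5 of 18 members called higher, 8 adjusted over the list alone, and 3 lower on that basis. The call was lost with an estimated correlation (adjusted p = 0.105), although the estimate, -0.024, lay below the preset 0.01. The members that rose were class II genes and their regulator. HLA-DRA was 4.99-fold higher, at 35.3 ± 6.49 against 7.04 ± 0.249 CPM (SD, n = 3 per group). HLA-DMB, which acts in loading peptide onto class II molecules, rose from a mean of 3.20 to 12.8 CPM (n = 3 per group, SE of the log2 fold change 0.18). HLA-DRB1 was 3.20-fold higher and CIITA, the class II transactivator, 1.91-fold higher (log2 fold change 0.94 ± 0.14, SE). The call of CIITA ended without MRT199665 replicate 1 (adjusted p = 0.0711) or 3 (0.135) and without vehicle replicate 2 (0.0587) or 3 (0.127). The lysosome and autophagy list was called higher (1 of 31 members, 4 adjusted over the list alone, adjusted p = 0.00380), with adjusted p = 0.135 with an estimated correlation and adjusted p = 0.109 without both libraries at the ends of the first component. Its called member CTSB, a lysosomal protease, was 2.29-fold higher and was not called without vehicle replicate 3 (adjusted p = 0.0656). Of 29 tested interferon response genes, IFI35 (1.73-fold) and OAS1 (3.67-fold, from a vehicle mean of 0.673 CPM) rose. When adjusted over the list alone 3 rose, while the list was not called (adjusted p = 0.0750). Neither IFI35 nor OAS1 was called when any 1 of the 6 libraries was left out (highest adjusted p = 0.197 for IFI35 and 0.191 for OAS1, both without MRT199665 replicate 3).

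**Figure D3:**
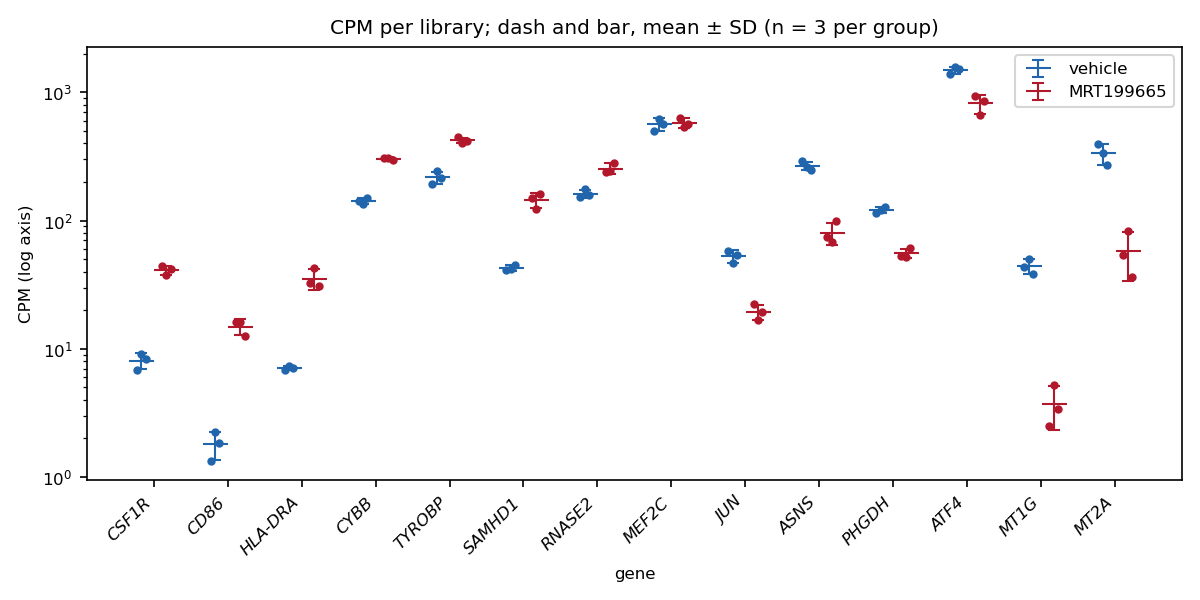
CPM (vertical, log axis) of 14 named genes in each library, with points for libraries, dashes for group means and bars for the SD (n = 3 per group). CSF1R lies near 41.1 CPM with MRT199665 and 8.08 CPM with vehicle, MT1G near 3.71 and 44.0 CPM, and MEF2C near 578 and 563 CPM.

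Genes of the unfolded protein and integrated stress response were lower as a list (median log2 fold change -0.48, camera adjusted p = 9.40e-08), also with an estimated correlation (adjusted p = 0.0409). Of 31 tested members, 7 fell, and 14 fell when adjusted over the list alone. The called members with the lowest p were ASNS, PHGDH, SESN2 and TRIB3. PHGDH, the first enzyme of serine synthesis, was 2.18-fold lower, at 55.4 ± 4.73 against 121 ± 6.41 CPM (SD, n = 3 per group). SESN2, a stress-induced regulator of nutrient signalling, was 1.84-fold lower and the pseudokinase gene TRIB3 2.07-fold lower. The transcription factor genes ATF5 and ATF4, the latter the main effector of the integrated stress response, were 1.89-fold and 1.82-fold lower. ATF4 stood at 819 ± 141 against 1489 ± 96.2 CPM (SD, n = 3 per group). Calls that ended without MRT199665 replicate 1 or 3 or vehicle replicate 3 were those of SESN2 (highest adjusted p = 0.0985, without vehicle replicate 3), TRIB3 (0.117, without MRT199665 replicate 3), ATF5 (0.126, without MRT199665 replicate 3) and ATF4 (0.211, without vehicle replicate 3). Those of ATF5 (adjusted p = 0.0517) and ATF4 (0.0993) also ended without vehicle replicate 2, and that of ATF4 without MRT199665 replicate 2 (0.0564).

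Metallothionein genes made up 4 of the 10 lower genes with the greatest fold changes that met the naming rule. Beside MT1G these were MT2A (5.84-fold lower, 57.7 ± 24.0 against 334 ± 63.0 CPM, SD, n = 3 per group), MT1X (4.58-fold lower) and MT1E (4.05-fold lower). These genes are close copies, so the assignment of reads between them is uncertain. ALDH1L2, a mitochondrial folate enzyme, was 4.73-fold lower, with a log2 fold change of -2.24 ± 0.17 (SE, adjusted p = 0.000694). ADM (adrenomedullin) was 4.69-fold lower, RETN (resistin) 4.25-fold lower and SYNPO2, an actin-binding protein, 4.06-fold lower. DACT3 (3.60-fold) and BLACE (3.56-fold) completed the group. MT1X was not called without MRT199665 replicate 2 or 3 or vehicle replicate 3 (highest adjusted p = 0.137, without MRT199665 replicate 3), nor was DACT3 without these or vehicle replicate 2 (highest 0.191, without MRT199665 replicate 3). BLACE was not called without MRT199665 replicate 3 (adjusted p = 0.0643) or vehicle replicate 3 (0.0904).

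Immediate early genes were lower as a list (camera adjusted p = 0.000179), with 3 of 27 members called, 5 adjusted over the list alone, and adjusted p = 0.0872 with an estimated correlation. The called members were the transcription factor genes JUN (2.70-fold lower, 19.5 ± 2.65 against 52.9 ± 5.85 CPM, SD, n = 3 per group), ETV4 (2.64-fold) and EGR1 (2.70-fold). EGR1 kept its call only without MRT199665 replicate 2 (highest adjusted p of the others 0.202, without vehicle replicate 3). The hypoxia list was lower (1 of 16 called, 3 adjusted over the list alone, adjusted p = 0.000415), but not with an estimated correlation (adjusted p = 0.309), and ADM was its called member. HILPDA, a lipid droplet protein among the abundant lower genes, was 2.59-fold lower and not called without MRT199665 replicate 1 (adjusted p = 0.0866), 2 (0.0533) or 3 (0.119). Of 23 glycolysis genes none was called by the main edgeR test, 1 fell when adjusted over the list alone, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom none. Of the members with the lowest p, SLC2A3 was called lower in 4 of 17 alternatives and ENO2 in 1. The glycolysis list was lower by camera (adjusted p = 0.0220) and not with an estimated correlation (adjusted p = 0.491). That call also ended without MRT199665 replicate 1 (adjusted p = 0.152) or 3 (0.154) or vehicle replicate 1 (0.0510). The glycolysis list's mean log2 CPM, centred per gene, was higher in MRT199665 replicate 2 (0.266) than in any other library, against -0.246 and -0.307 in MRT199665 replicates 1 and 3. The NF-kB and inflammatory list was lower (1 of 19 called, 6 adjusted over the list alone, adjusted p = 0.0291), with adjusted p = 0.468 with an estimated correlation. It was not called without MRT199665 replicate 2 (adjusted p = 0.0526) or 3 (0.125) or vehicle replicate 2 (0.0725), nor without both ends of the first component (0.134) or without a low-count filter (0.345). Its called member, the chemokine gene CCL5, was 1.69-fold lower and kept its call only without vehicle replicate 1 (highest adjusted p of the others 0.187, without vehicle replicate 3).

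Genes of the cell cycle lists mostly had negative log2 fold changes of small size. The list of genes expressed in G2 and mitosis had a median log2 fold change of -0.28, with 46 of 53 members negative (camera adjusted p = 3.24e-08, and adjusted p = 0.0409 with an estimated correlation). None of the 53 was called by the main edgeR test over all genes or adjusted over the list alone, while 22 had an unadjusted p under 0.05, all negative, and DESeq2 called 2 and limma-voom none. The members with the lowest p were HMMR (log2 fold change -0.59 ± 0.13, SE, adjusted p = 0.0840) and PTTG1 (-0.63 ± 0.15, SE, adjusted p = 0.0995). HMMR and PTTG1 were each called in 2 of 17 alternatives. The list of genes of the G1/S transition was also lower (37 of 47 negative, adjusted p = 0.000890), with adjusted p = 0.309 with an estimated correlation. DNA repair genes (26 of 34 negative, adjusted p = 0.0147) were not called with an estimated correlation (adjusted p = 0.180). The list of MYC targets and ribosome biogenesis was lower (31 of 38 negative, adjusted p = 0.00228), but not with an estimated correlation (adjusted p = 0.337) or without MRT199665 replicate 2 (adjusted p = 0.0526). Heat shock genes (15 of 18 negative, adjusted p = 0.00252) lost the call with an estimated correlation (adjusted p = 0.309) and without vehicle replicate 1 (adjusted p = 0.0600). Cholesterol synthesis and uptake genes (24 of 29 negative, 2 lower adjusted over the list alone, adjusted p = 0.00308) had adjusted p = 0.309 with an estimated correlation. The groups overlapped, since the cholesterol list's mean log2 CPM, centred per gene, was 0.0537 in MRT199665 replicate 2 and 0.0007 in vehicle replicate 2. Cytosolic ribosomal protein genes were higher as a list (61 of 76 positive, adjusted p = 0.00428), though not with an estimated correlation (adjusted p = 0.468) or without MRT199665 replicate 2 (adjusted p = 0.172). Without both ends of the first component neither the MYC list (adjusted p = 0.109) nor the ribosomal protein list (0.489) was called. In these 6 lists the main edgeR test called no single gene and, except for cholesterol, none adjusted over the list alone. Of the members with the lowest p, MSMO1 was called in 3 of 17 alternatives, and FDFT1, HSPD1, RPL30 and XRCC1 in 1 each. Unadjusted p fell under 0.05 for 10 genes of the G1/S list, 2 ribosomal protein genes and 5 in each of the others, and DESeq2 called 2 cholesterol genes and none elsewhere, limma-voom none.

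**Figure D4:**
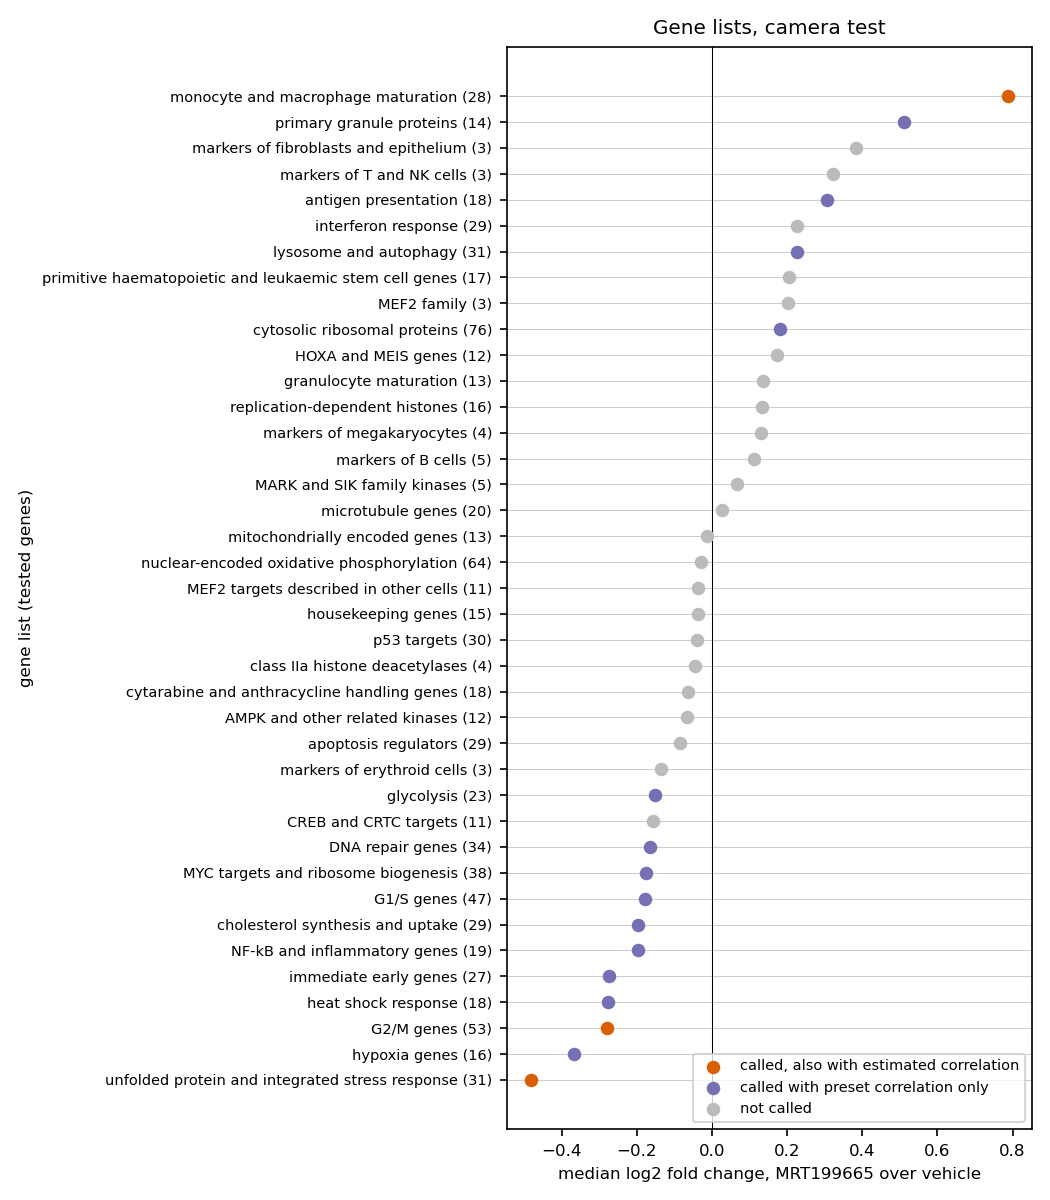
Median log2 fold change (MRT199665 over vehicle, horizontal) of the 39 gene lists, with the number of tested genes in parentheses. Colour marks the 16 lists called by camera at a preset correlation and the 3 of them also called with an estimated correlation, at medians of 0.79, -0.28 and -0.48.

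The transcripts of the kinases named as targets, and of MEF2C itself, did not pass the test. MEF2C, a transcription factor expressed in these cells at 578 ± 49.4 CPM with MRT199665 and 563 ± 64.1 CPM with vehicle (SD, n = 3 per group), had a log2 fold change of 0.04 ± 0.13 (SE, adjusted p = 0.941). MEF2A was at 0.20 ± 0.18 (SE). MEF2D was at 0.32 ± 0.37 (SE), with 161 CPM in MRT199665 replicate 2 against 55.1 and 68.5 CPM in the other treated libraries, and turned to -0.29 without that library and to -0.43 without both ends of the first component. MEF2B had a count of 0 in all 6 libraries. SIK3 had the lowest p of the MARK and SIK genes, with a log2 fold change of 0.61 ± 0.16 (SE, adjusted p = 0.121), and rose when adjusted over the list alone. MARK2, MARK3, MARK4 and SIK2 had log2 fold changes of 0.07, 0.12, -0.07 and -0.13, with SE between 0.10 and 0.18. MARK1 had a count of 0 in all libraries, and SIK1 had between 3 and 10 counts per library and was not tested. The class IIa histone deacetylase genes HDAC4, HDAC5, HDAC7 and HDAC9, whose products are bound by MEF2 factors, had log2 fold changes of 0.05, 0.27, -0.14 and -0.15. Over these 12 tested genes the main edgeR test, DESeq2 and limma-voom called none, and 1 (SIK3) had an unadjusted p under 0.05. In 1 of 17 alternatives, another edgeR setting, SIK3 was called (adjusted p = 0.0281). The lists of the MEF2 family (adjusted p = 0.652), MARK and SIK kinases (0.591) and class IIa deacetylases (0.994) were not called. Of 11 tested MEF2 targets described in other cells, TGFBI, a secreted adhesion protein, was 1.97-fold higher and JUN lower, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.994). TGFBI was not called without vehicle replicate 3 (adjusted p = 0.0703). CREB and CRTC targets (adjusted p = 0.404) and AMPK and other related kinases (0.164) were not called either. The medians of the MEF2 target list (-0.04) and the class IIa list (-0.04) were negative and their test direction was higher, with means of -0.05 and 0.01.

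SAMHD1, a triphosphohydrolase that hydrolyses deoxynucleotides and the active form of cytarabine, was 3.38-fold higher, at 144 ± 18.7 against 42.8 ± 2.20 CPM (SD, n = 3 per group), with a log2 fold change of 1.76 ± 0.13 (SE, adjusted p = 0.000694). It was the called member of the 18 tested cytarabine and anthracycline handling genes, also adjusted over the list alone. That list was not called (adjusted p = 0.838), with a negative median (-0.06) and test direction and a positive mean (0.06). Among 16 tested histone genes, HIST1H2AC (2.29-fold), HIST1H2BK (2.42-fold) and HIST1H3D (2.84-fold) rose and 2 genes including HIST1H1B (1.88-fold) fell, against 4 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.747). Each of these 4 named histone calls ended at least without MRT199665 replicate 1 and without vehicle replicate 3, with a highest adjusted p of 0.223 for HIST1H1B (without vehicle replicate 3). In the p53 target list SESN2 was the called gene of 30 tested, and 2 fell adjusted over the list alone (list adjusted p = 0.424). Apoptosis regulators (adjusted p = 0.591), the HOXA and MEIS list (0.0970), primitive haematopoietic and leukaemic stem cell genes (0.351) and granulocyte maturation genes (0.112) were not called, though the granulocyte list was called in 5 of 16 alternatives (lowest adjusted p = 0.0282). Adjusted over the list alone, 3 of the stem cell genes rose and 1 fell, and 2 granulocyte genes rose. CXCR4, a chemokine receptor of the granulocyte list, had a log2 fold change of 0.47 ± 0.10 (SE, adjusted p = 0.0753). Nuclear-encoded oxidative phosphorylation (adjusted p = 0.591), mitochondrially encoded genes (0.626), microtubule genes (0.709) and housekeeping genes (0.591) were not called. Medians and means differed in sign for oxidative phosphorylation (-0.03 and 0.00) and microtubule genes (0.03 and -0.01), both with a lower test direction. Of the markers of other cell types, those of B cells (adjusted p = 0.896), erythroid cells (0.902), megakaryocytes (0.591) and fibroblasts and epithelium (0.709) were not called, with 5, 3, 4 and 3 genes tested. Among these, 2 megakaryocyte markers rose when adjusted over the list alone.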

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

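The settings chosen after seeing the data were the newer quasi-dispersion, the GC removal and the omission of both ends of the first component. All 163 calls kept their sign in each setting that tested them. Against 111 higher and 52 lower genes, DESeq2 called 215 and 148 (159 shared) and edgeR without a low-count filter 373 and 271 (163 shared, with 28230 genes tested), and the cause was not tested. Leaving out single libraries gave between 29 and 78 higher and between 20 and 55 lower genes, with 49 to 111 of the 163 shared, in fits with fewer samples. Without both ends of the first component 92 and 45 were called (111 shared). The other scalings, filters, limma-voom, the newer quasi-dispersion and the GC removal stayed within 1.5 times, at 103 to 114 higher and 50 to 60 lower. Of 53 called named genes, 24 kept the call without each single library.

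Correlations of deviations between libraries with the same number were -0.547, -0.467 and 0.018, which gave no sign of pairing. Deviations were taken from means of 3 libraries, and the first component held 46.75% of the variance, so pairing by number cannot be excluded. With the number as a replicate block 7 higher and 5 lower genes were called, all among the 163, and 16 lists. The named genes that kept the call with this block were ALDH1L2, AMICA1, CD86, CSF1R, HLA-DRA, LILRB2, MT1E, MT1G, MT2A and SAMHD1. All other named genes lost it, among them JUN (adjusted p = 0.0616), ASNS (0.0672), PHGDH (0.0762) and CYBB (0.0897), which had kept it without each single library. No library correlated best with the library of its own number in the other group.

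Of 16 lists called, 3 were called with an estimated correlation, 11 lists with fry (8 shared) and between 14 and 17 without single libraries. For the antigen presentation (-0.024), immediate early (-0.022), DNA repair (-0.013) and lysosome (-0.004) lists the estimated correlation lay below the preset 0.01. A higher correlation thus did not end these calls, and fry called these lists (adjusted p = 0.0021, 0.0021, 0.0215 and 0.0266). Fry did not call the hypoxia (adjusted p = 0.0704), MYC (0.0818), heat shock (0.098), G1/S (0.103) and cholesterol (0.120) lists. Nor did it call the NF-kB (adjusted p = 0.120), ribosomal protein (0.224) and glycolysis (0.349) lists. Without both ends of the first component camera called 13 lists. Of the lists not called, granulocyte maturation was called in 5 of 16 alternatives, nuclear-encoded oxidative phosphorylation in 2, and the AMPK and other related kinases, interferon response and T and NK cell marker lists in 1 each. All 6 libraries form 10 splits into groups of equal size, so a share under 0.05 cannot be reached. The real split was the 1 with 163 called genes, against at most 0 in the others, although the other split with most genes at an unadjusted p under 0.05 had 2163 against 1925. It parted the libraries along the first component. For lists the real split was the 1 with 16, against between 2 and 7 in the others, so every other split also called lists. Depth limits what can be said of genes at few CPM.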

Other observations

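The gene groups and tests of this part were chosen after the results were seen, so the p-values describe the groups and are not separate support. The 7 camera tests were adjusted together. Within the stress response list, genes of the ATF4 arm moved apart from genes of endoplasmic reticulum chaperones. Of 19 tested ATF4-arm genes 18 had a negative log2 fold change and 7 fell, with a median of -0.71 (camera adjusted p = 4.82e-15, and adjusted p = 0.0101 with an estimated correlation). Of 12 chaperone-arm genes 8 were positive and 4 negative, with log2 fold changes from -0.37 to 0.89, none of them called, and HSPA5 was at 0.09 ± 0.15 (SE) (camera adjusted p = 0.683). Cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNAs with amino acids, were negative for 18 of 20 (median -0.32, adjusted p = 1.44e-06, and adjusted p = 0.0135 with an estimated correlation), and GARS (1.68-fold lower, adjusted p = 0.0238 by edgeR) and YARS (log2 fold change -0.70 ± 0.11, SE) fell.

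All 6 tested metallothionein genes fell (median log2 fold change -2.37, camera adjusted p = 2.44e-13, and adjusted p = 0.0163 with an estimated correlation), although the split of reads between these copies is uncertain. The list had a mean centred level of -1.40, -1.02 and -1.45 in MRT199665 replicates 1 to 3 and 1.35, 1.44 and 1.08 in the vehicle libraries.

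All 9 tested genes of a class II pathway group, which held CIITA, CD74 and CTSS beside 6 class II HLA genes, had a positive log2 fold change and 5 rose, among them CIITA (median 1.68, adjusted p = 6.43e-12, and adjusted p = 0.0101 with an estimated correlation). The 9 genes of a class I pathway group, which held HLA genes, B2M, TAP1, TAP2, TAPBP and NLRC5, were not called as a list (4 positive and 5 negative, median log2 fold change -0.04, camera adjusted p = 0.251, which compares with other genes). Their mean log2 change was -0.149 ± 0.025 (SE over libraries), with all treated libraries below all vehicle libraries. This mean was drawn down by TAP2, while the median was -0.04. The mean log2 change of the class II pathway group lay 1.52 ± 0.11 (SE over libraries) above that of the class I pathway group. The lowest value in the class I pathway group was that of TAP2, a peptide transporter of the class I pathway, with a log2 fold change of -1.01 ± 0.20 (SE, adjusted p = 0.0553). Linker histone genes were lower (4 of 5 negative, 2 called, adjusted p = 0.000815, and adjusted p = 0.0444 with an estimated correlation).

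Monocyte and macrophage genes were higher with MRT199665. Blood monocytes mixed into the treated cultures would bring their most abundant transcripts, but the sum of LYZ, S100A12, VCAN, FCN1 and CD14 was higher by 2.72 ± 0.79 CPM (SE, unscaled totals), against 32.7 ± 1.76 CPM for CSF1R alone. Of these 5 genes, 2 passed the count filter and 4 belong to the maturation list, and LYZ reached 3.58 CPM. The shallow library MRT199665 replicate 2 did not carry the pattern, since without it the list's median log2 fold change was 0.61 against 0.79, and removal of the GC trend left it at 0.78. A response of the cells to the inhibitor is a hypothesis that may account for the pattern, and which kinase would be involved was not tested.

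For the fall of ATF4-arm genes, vehicle replicate 1 alone was not the source: the median log2 fold change without it was -0.736 against -0.711. Removal of the GC trend gave -0.744. The chaperone arm lay 0.877 ± 0.123 (SE) above the ATF4 arm in mean log2 change and at 0.092 ± 0.130 (SE) itself. These chaperone genes thus did not fall as a group. Both arms were chosen after the results were seen. The gap between them therefore cannot decide whether the unfolded protein response fell as a whole. A response of the cells to the inhibitor stays open as a hypothesis, and how it would lower these genes was not tested.

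Libraries spread along the first principal component within both groups. Scores were -10.4, 48.4 and 6.23 in MRT199665 replicates 1 to 3 and 10.6, -36.8 and -18.0 in vehicle replicates 1 to 3. The gap between MRT199665 replicate 2 and vehicle replicate 2 was 0.746 log2 units per gene (root mean square). It lies between a treated and a vehicle library, so it includes any treatment difference. Thinning all libraries to the smallest total left 0.722, and removal of the GC trend left 0.727 against 0.729. Neither the difference in totals alone nor the GC trend accounts for the gap. Thinning leaves the counting noise of the shallow library itself, so an effect of its low depth is not excluded. Library size had Pearson r = -0.939 with the component of protein-coding genes within MRT199665 and 0.061 within vehicle (n = 3 per group). Over 9720 protein-coding genes without a named pseudogene it was 0.696 against 0.707 for 10800 protein-coding genes, which argues against reads shared with pseudogenes as the whole source. The share of counts on pseudogenes, from 0.570% to 0.858%, had Pearson r = -0.794 (permutation p = 0.0486, adjusted 0.146) and Spearman rho = -0.771 (permutation p = 0.103, adjusted 0.309) with the component of protein-coding genes over the 6 libraries, among 3 relations computed, and r = -0.862 without the 2 libraries farthest from the median. The labels give no batch, and a difference between cultures or library preparations may remain as an explanation, beside treatment and depth.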
